A study of Homo sapiens with 4 samples.

How the data were processed

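Poly(A) RNA of untreated U2OS cells was immunoprecipitated with an anti-m7G antibody, and input and IP libraries were made with a stranded mRNA kit and sequenced on an Illumina instrument, per the labels' protocols. The series has 4 samples, 2 input and 2 IP, grouped by their titles. The input libraries enter here only through the authors' own peak calls. STAR and the genome build GRCh38 are named in the submitters' processing notes, without a version. The peak caller and its settings are not given in the sources used here. Peaks were deposited as 1 table for each IP replicate, so they were called for each replicate and not on pooled libraries.

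Each deposited table gives, per the file headers, a p-value for every peak, its log10 and the log10 of a false discovery rate, which are treated as a score, and a fold enrichment of IP over input, a linear ratio. How the authors scaled that fold for library size is not given in the sources used here. The weakest false discovery rate was 0.0490 in replicate 1 and 0.0479 in replicate 2, so the tables hold peaks past a threshold and nothing below it. No counts were given, so depth is unknown and no interval for a single peak's fold can be set. The spread between replicates over shared peaks is given in its place. It leaves out peaks found in a single replicate and pools all folds, so it can understate the error of a peak's fold.

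Peak blocks were compared on the same strand, and a peak was shared if it overlapped a peak of the other table by at least 1 bp. Mutually best overlaps were kept as pairs. Gene names were taken from the tables and matched to the RefSeq gene table of GRCh38.p14, which gives symbols, synonyms, biotype and span but no strand or transcripts. A symbol was accepted if its gene lay within 2000 nt of the peak. This matched 99.8% of peaks in replicate 1 (196 through a synonym) and 99.7% in replicate 2 (221 through a synonym), and 9 and 13 peaks were left unmatched. The tables held 6 and 11 rows that repeat the position of another row under a different gene name. Coordinates are 1-based.

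Random placements (1000) kept each peak in its own gene span, and overlap and gene-start shares were tested one-sided against them. Intervals for shares are Wilson 95% intervals and cover counting error only. Distances run from the midpoint of the joined blocks to the annotated gene start or end, and 200 nt on either side counted as near the start. Mean log2 folds were compared by permuting labels 100000 times, two-sided. Each list's coverage was tested against 10000 random lists of protein-coding genes matched on decile of gene span, and its strength, the median log2 fold of each gene's strongest shared peak, against 10000 random lists of genes with a shared peak, for lists with at least 5 such genes. The p-values over lists were adjusted by Benjamini-Hochberg. Of 22 fixed lists, 21 were tested: the 13 mitochondrially encoded genes had no match in the gene table.

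Lists, tests and the rule for named genes were fixed before the data were examined. The rule names the 10 protein-coding genes with the highest lower-of-both-replicates fold, up to 3 genes for each list by the same order, METTL1, WDR4, QKI, G3BP1, YAP1, TEAD1 and CCND1 in any case, the 3 genes with the most shared peaks and the 3 highest peaks of each replicate alone. Further genes, such as HNRNPU, KMT2B, CREBBP, ACTB, CFL1 and COL1A1, were chosen after their values were seen. With neither a genome nor transcript models used here, the planned tests of transcript regions, the GANGAN motif, hexamers and GC content were not run, nor was the part of the naming rule that needs transcript regions. Placement in gene spans, matching on gene span and distances to gene ends replaced the planned use of spliced transcripts and were chosen after the tables had been seen.

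The overlap search and list tests were tested on simulated data first. Of simulated replicate 1 peaks 60.3% were truly shared and 60.5% were found shared. For gene list coverage over 20056 genes, 4% of unchanged lists passed p under 0.05, and 89% of lists with 30% against 10% coverage did. For gene list strength over 2108 genes, 7% of unchanged lists passed and 90% of lists shifted by 1 log2 unit did. Alternatives were a stricter overlap, midpoints within 100 nt, the more significant peaks of each table, a fold of at least 4, each replicate left out, other backgrounds and other summaries for each gene. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.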

Results

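Antibody enrichment for N7-methylguanosine (m7G), a positively charged methylated guanine that forms the cap of mRNA and has also been mapped inside mRNA, was measured in untreated U2OS cells. U2OS is an established human osteosarcoma line of mesenchymal, bone-derived character. Poly(A) RNA was immunoprecipitated with an anti-m7G antibody, and 2 input and 2 immunoprecipitated (IP) libraries were sequenced. The values used here are the 2 tables of peaks, 1 for each IP replicate, in which every peak has a position, a fold enrichment over input, a p-value and a false discovery rate. These per-peak values are the authors' own. IP replicate 1 held 4326 peaks naming 3194 protein-coding genes, and IP replicate 2 held 4862 peaks naming 3479. Peaks were short, with a median length of 151 nt in both replicates, and 30.8% and 34.7% of them were listed as more than 1 block. The median fold was 4.27 in replicate 1 (interquartile range 2.56 to 7.12) and 3.48 in replicate 2 (2.14 to 5.56). The tables carry no read counts, so the depth behind each peak is unknown. The labels do not say whether the replicates came from separate cultures, and the spread between them may be technical.

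The first question was which mRNAs carried a peak at the same place in both replicates. By the lower fold of both replicates, the highest lay on SNX8, a sorting nexin of endosomes (98.7-fold in replicate 1 and 110-fold in replicate 2). SYNCRIP, an RNA-binding hnRNP (87.9 and 95), came next, then a peak named for INS (167 and 80) and POU3F3, a neural transcription factor (74 and 135). LAMTOR1, the membrane anchor of the Ragulator complex (111 and 70), NUS1, a subunit of the enzyme that makes dolichol (167 and 60), and CHD3, a nucleosome remodeller of the NuRD complex (58 and 64.4), followed with PTPN11, the tyrosine phosphatase SHP2 (55.5 and 60). CELSR3, an adhesion receptor of the cadherin family, reached 55.5 and 50, and MDFI, an inhibitor of myogenic transcription factors, 43.2 and 63.3. The annotated span of INS-IGF2 also covers the INS peak. Other annotated spans also cover the LAMTOR1 peak (LRTOMT), the CHD3 peak (NAA38) and the PTPN11 peak (RPL6), and the gene table gives no strand for them.

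Positions are those of GRCh38. The SNX8 peak lay on chromosome 7 from 2252430 to 2253119, minus strand, 1005 nt from the annotated gene end. The SYNCRIP peak lay on chromosome 6 from 85642966 to 85643325, minus strand, 724 nt inside the annotated gene start. The strongest POU3F3 peak lay on chromosome 2 from 104855261 to 104855709, plus strand, and POU3F3 carried 6 shared peaks in all. The CHD3 peak lay on chromosome 17 from 7884805 to 7885074, plus strand, with its midpoint 144 nt from the annotated gene start, and the gene had 5 shared peaks. AGRN, which encodes the basement membrane proteoglycan agrin, had the most shared peaks, 7, with folds of 2.37 and 1.84 at the strongest. SCAF1, which encodes an SR-related splicing protein, had 6, with 8.20 and 7.17 at the strongest. Exon, intron and untranslated-region annotation was not used here.

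Of the replicate 1 peaks, 2708 (62.6%, Wilson 95% interval 61.1 to 64.0) overlapped a replicate 2 peak by at least 1 bp on the same strand, and of the replicate 2 peaks 2717 (55.9%, 54.5 to 57.3) overlapped a replicate 1 peak. For comparison, the replicate 2 peaks were placed at random within the annotated spans of their own genes. Over 1000 placements they overlapped a mean of 5.28% and a maximum of 6.30% of replicate 1 peaks (one-sided permutation p = 0.001, the smallest these can give). Spans include introns, which lowers the share expected by chance. In genes spanning up to 5000 nt, where introns take less room, 69.0% of peaks overlapped against a random mean of 20.5%. Sharing followed significance: 28.6% of the least significant 20% of replicate 1 peaks were shared and 98.8% of the most significant 20%, with 23.4% and 93.2% in replicate 2. The mutually best overlaps made 2653 shared peaks.

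At the level of genes, 2334 protein-coding genes had a peak in both tables, 73.1% of those in replicate 1 and 67.1% of those in replicate 2, where independent lists of these sizes would share 554 (odds ratio 37.3, over 20056 annotated protein-coding genes). Genes that U2OS cells do not express inflate that ratio. Of the 1313 genes with 1 peak in each replicate, 1141 (86.9%, Wilson 85.0 to 88.6) had it at the same place. A shared peak was present on 2108 protein-coding genes, 10.5% of all.

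The fold of a shared peak was similar in both replicates. ARPC2, a subunit of the actin-nucleating Arp2/3 complex, had 20.9 and 16.4, TAF15, an RNA-binding protein of the FET family, 9.85 and 9.71, and HNRNPD 9.74 and 10.3. Larger gaps were seen at PUM2, a translational repressor (14.8 and 40), and at the transcription factor TEAD2 (24.7 and 6.05), where the span of DKKL1 also covers the peak. Across the 2653 shared peaks, which are not independent replicates, Spearman's rho was 0.879 (bootstrap 95% interval 0.866 to 0.889) and Pearson's r on log2 folds was 0.860. The median absolute difference was 0.30 on the log2 scale, a factor of 1.23, and 95% of shared peaks differed by less than 1.28, a factor of 2.42. A fold of at least 4 in both replicates was reached by 1135 shared peaks (42.8%).

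**Figure D1:**
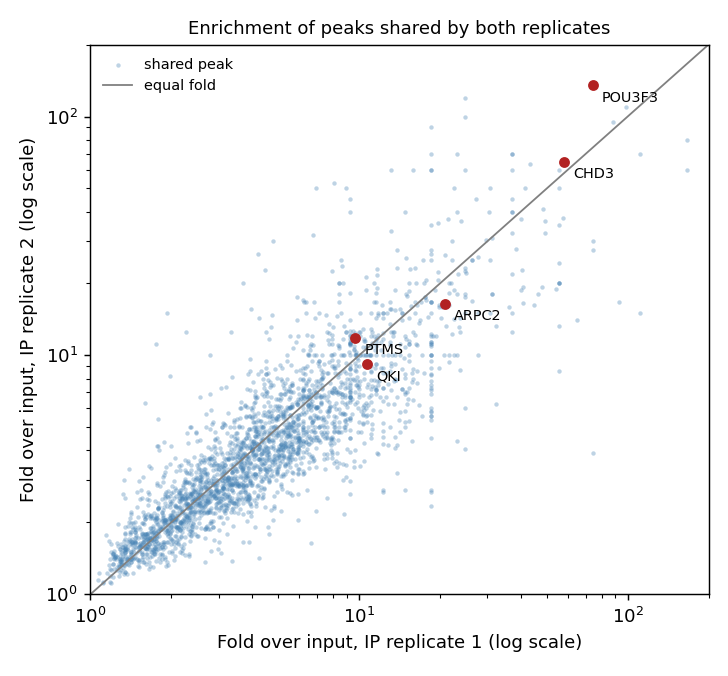
Fold enrichment over input of the 2653 shared peaks in IP replicate 1 (x) and IP replicate 2 (y), both on log axes, with 5 genes marked in red and the line of equal fold in grey. Most points lie close to the line (rho 0.879), and the points at high fold fall on vertical and horizontal rows.

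Many high folds were whole multiples of a single value, a feature noticed only after the data had been examined. In replicate 1 the most frequent fold of at least 10 was 18.5, held by 67 peaks. Whole multiples of it (within 0.05, or 0.5 from a fold of 100) made up 134 of the 253 peaks at or above it (53.0%), against at most 6.37% for 38 other step sizes. In replicate 2 the most frequent was 10, and 148 of 509 peaks (29.1%) were whole multiples, against at most 8.82%. INS, LAMTOR1, NUS1, PTPN11 and CELSR3 were at such values in both replicates, SNX8 and POU3F3 in 1 of them, and SYNCRIP, CHD3 and MDFI in neither. Other named genes were at such values too, such as CLK2 in both replicates, BMP1 and ACTN4 in replicate 1, and PUM2 in replicate 2. So were the highest peaks found in a single replicate, given below. Fold and significance were nearly unrelated within a table (Spearman's rho of fold with -log10 p 0.138 and 0.109 across peaks). The CELSR3 peak had log10 p of -5.30 and -4.55, and the CHD3 peak -92.4 and -74.7.

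The next question was where along the gene the peaks lay, since the cap at the mRNA 5′ end is itself m7G. Shared peaks lay at gene starts more often than under random placement in gene spans. Among them were those of NUS1 (90 nt from the annotated start), PTPN11 (10 nt) and CELSR3 (166 nt). Another was that of FXR2, a paralog of the fragile X protein (119 nt, 26.4- and 25-fold), which the span of SHBG also covers. The midpoints of 622 of 2648 shared peaks (23.5%, Wilson 21.9 to 25.1) lay within 200 nt of the annotated start. Random placement in the gene span gave 0.855% (one-sided permutation p = 0.001), and in genes spanning up to 5000 nt the shares were 26.5% and 3.55%. Spans include introns, which lowers the random share. Observed midpoints up to that distance outside the span, such as that of BMP1, also counted as near, while random midpoints always lay inside it. An excess was therefore likely in advance and its size is uncertain. The shares near the gene end below were counted in the same way. Placement along spliced transcripts was not run. By span, 40.8% of shared peaks fell in the first 10% of the gene and 22.8% in the last 10%. Peaks toward the other end included those of ARPC2 (368 nt from the annotated gene end), MDFI (193 nt) and ACIN1, an RNA-processing protein (763 nt). Within 1000 nt of the gene end lay 15.3% of shared peaks against 8.27% at random, but in genes spanning up to 5000 nt it was 29.1% against 36.0%, so no excess was seen there at that distance. Within 200 nt of the gene end lay 2.61% against 0.85% at random (one-sided permutation p = 0.001). In genes spanning up to 5000 nt it was 5.11% against 3.51% (one-sided permutation p = 0.0939).

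Peaks at gene starts had the higher folds. Their mean log2 fold was 2.58 ± 1.07 (SD, n = 622) against 1.98 ± 1.06 (n = 2026) for other shared peaks, a difference of 0.60 (bootstrap 95% interval 0.50 to 0.70, two-sided permutation p = 1e-05, the smallest these permutations can give). In medians, gene-start peaks reached 5.70-fold, peaks within 1000 nt of the gene end 3.24-fold and peaks elsewhere 3.72-fold. Peaks over 200 nt from the start and over 1000 nt from the end were nonetheless the most frequent class, 1621 of 2648 (61.2%). Some lay close to the start, since 951 of all 2648 lay within 500 nt of it. Strong ones on PUM2 and POU3F3, of 1 block in both replicates, lay 1567 and 2209 nt from the annotated start. Distances are genomic, and 31.0% of shared peaks had more than 1 block in both replicates. The midpoint of such a peak can lie an intron away from a block at the start, so this class may hold peaks that reach the start. The TEAD2 peak, with 2 blocks and its midpoint at 2355 nt, may be one of them. Without transcript models, peaks at other transcript starts cannot be told from internal ones. In replicate 2, shared peaks lay at gene starts more often than peaks found only there (22.8% against 14.3%, Fisher's exact test, two-sided, adjusted p = 9.43e-14). In replicate 1 the shares were 23.2% and 21.3% (Fisher's exact test, adjusted p = 0.152).

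**Figure D2:**
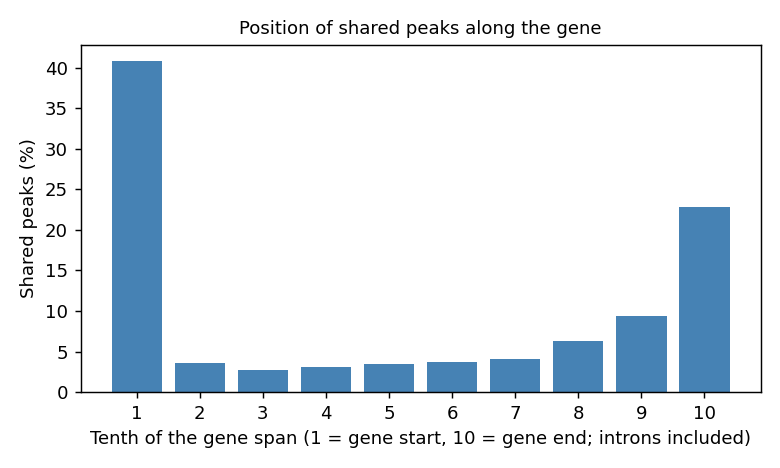
Share of the 2648 shared peaks (y, percent) in each 10% of the annotated gene span from start to end (x), introns included. The first bar holds 40.8% of the peaks and the last 22.8%.

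Gene lists fixed before the data were examined were then asked which groups of mRNAs carried shared peaks. Coverage was highest for the actin cytoskeleton, with a shared peak on 29 of 41 members (70.7%), followed by splicing factors with 29 of 54 (53.7%). Stress granule proteins, which gather with stalled mRNA, had 21 of 42 (50%), and genes of the extracellular matrix and osteoblast lineage 20 of 40 (50%). Random lists of the same size, matched on gene span, averaged 10.5 to 11.6% for these 4 lists. In all, 13 of the 21 lists tested had higher coverage than random lists at an adjusted p under 0.05 and 0 had lower (two-sided permutation test, Benjamini-Hochberg over the 21 lists, adjusted p = 0.000525 for each of the 4 lists above). Expression is not measured in these tables, and a gene that is not expressed cannot carry a peak.

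Among actin cytoskeleton mRNAs, ARPC2 stood beside ACTN4, the cross-linker alpha-actinin 4 (18.5 and 12), and SPTBN1, a spectrin (9.63 and 12.4). Most others had low folds, such as ACTB, which encodes beta-actin (1.63 and 1.55), and CFL1, which encodes cofilin (1.26 and 1.30). Splicing factors included CLK2, a kinase of SR proteins (55.5 and 20), HNRNPD, ACIN1 (8.33 and 9.46) and HNRNPU (7.91 and 9.01). Stress granule mRNAs were led by FXR2, PUM2 and TAF15, while G3BP1, the core granule protein, had a weak peak (1.72 and 1.48). Matrix genes included BMP1, the procollagen C-proteinase (37 and 32.5), COL6A1 (11.5 and 8.84) and COL5A1 (8.30 and 14.6, with 5 shared peaks), and COL1A1, the main bone collagen, had 4.60 and 6.38.

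Translation factors carried shared peaks on 20 of 43 members (46.5%, adjusted p = 0.000525, permutation). Among them were EIF4H at 5.40 and 5.00 and EIF4G1, the scaffold of the cap-binding complex, at 4.63 and 11.7. EIF3C (4.43 and 5.82) has a near-identical copy, so its value is uncertain. Ribosomal protein mRNAs carried them on 31 of 79 (39.2%, adjusted p = 0.000525, permutation), led by RPS2 (5.31 and 5.64) and RPS23 (3.83 and 3.79). Reads of ribosomal protein genes can also match their many processed copies. Glycolysis had 8 of 18 (44.4%, adjusted p = 0.00267, permutation), with PFKL at 9.96 and 6.92 but GAPDH at 1.58 and 1.72, and chaperones 13 of 36 (36.1%, adjusted p = 0.000933, permutation), with HSP90B1 at 6.58 and 6.30.

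Hippo signalling, the pathway that restrains YAP1, had shared peaks on 15 of 36 members (41.7%, adjusted p = 0.000525, permutation). YAP1 itself had 5.89 and 6.27 at 209 nt from its annotated gene start, TEAD1, its DNA-binding partner, 11.7 and 3.90, the kinase TAOK2 11.1 and 10.8 (the span of LOC124903762 also covers this peak), and AJUBA 6.94 and 6.02. The m6A machinery had 8 of 19 (42.1%, adjusted p = 0.00126, permutation), with the methyltransferase METTL16 at 6.94 and 7.83 and the reader YTHDC1 at 5.26 and 5.17. Chromatin remodellers had 18 of 52 (34.6%, adjusted p = 0.000525, permutation), and besides CHD3 these included SMARCC2 (16.9 and 14) and SMARCC1 (32.4 and 13.3) of the SWI/SNF complexes. Ubiquitin and proteasome genes had 10 of 33 (30.3%, adjusted p = 0.00525, permutation), with USP7 at 16.1 and 23.3, and oxidative and integrated stress response genes 8 of 28 (28.6%, adjusted p = 0.0207, permutation), with ATF5 at 6.17 and 6.43. Both of these calls ended with 50% reciprocal overlap (adjusted p = 0.078 and 0.1, permutation) and in the more significant peaks of each table (adjusted p = 0.163 and 0.337).

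The remaining 8 lists did not pass the test. Cell cycle and mitosis had 9 of 54 members with a shared peak (16.7%), DNA damage response 7 of 36 (19.4%) and replication-dependent histones 2 of 28 (7.14%). With all peaks of a single replicate, cell cycle and mitosis passed without replicate 1 (19 of 54, adjusted p = 0.0087, permutation) and without replicate 2 (20 of 54, adjusted p = 0.00267), and DNA damage response passed without replicate 1 (13 of 36, adjusted p = 0.0356) but not without replicate 2 (10 of 36, adjusted p = 0.175). CCND1, which encodes cyclin D1, had 2 shared peaks (3.01 and 3.47 at the stronger), INCENP 4.41 and 3.97, and GADD45A 8.02 and 13.1. Of the markers of other cell types, haematopoietic and hepatocyte markers had 0 of 17 each, neuronal markers 2 of 16 (SLC17A7 and NEFL; 12.5% against 11.3% in random lists) and epithelial markers 2 of 17 (CLDN4 and KRT18, whose peak the span of KRT8 also covers; 11.8% against 10.5%). No peak of either replicate lay on the mitochondrial genome, and that list was not tested.

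Fewer lists passed when only genes with a peak in either replicate were compared, which does not remove differences in expression level. Then 5 lists had a shared peak more often than random lists of such genes: actin cytoskeleton (90.6% of 32 genes, adjusted p = 0.002, permutation), extracellular matrix and osteoblast lineage (87.0% of 23, adjusted p = 0.002), translation factors (76.9% of 26, adjusted p = 0.047), stress granule proteins (75% of 28, adjusted p = 0.036) and splicing factors (70.7% of 41, adjusted p = 0.0472). Among the lists that lost the call, the excess over random lists stayed about as large for the m6A machinery (30.9 percentage points against 30.8) and Hippo signalling (28.3 against 31.6). It fell further for the others, as for ribosomal proteins (10.5 against 28.9). With a fold of at least 4 required in both replicates, a setting added after the results had been seen, 4 lists passed: splicing factors (12 of 54), chromatin remodellers (11 of 52), stress granule proteins (9 of 42) and extracellular matrix and osteoblast lineage (8 of 40).

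**Figure D3:**
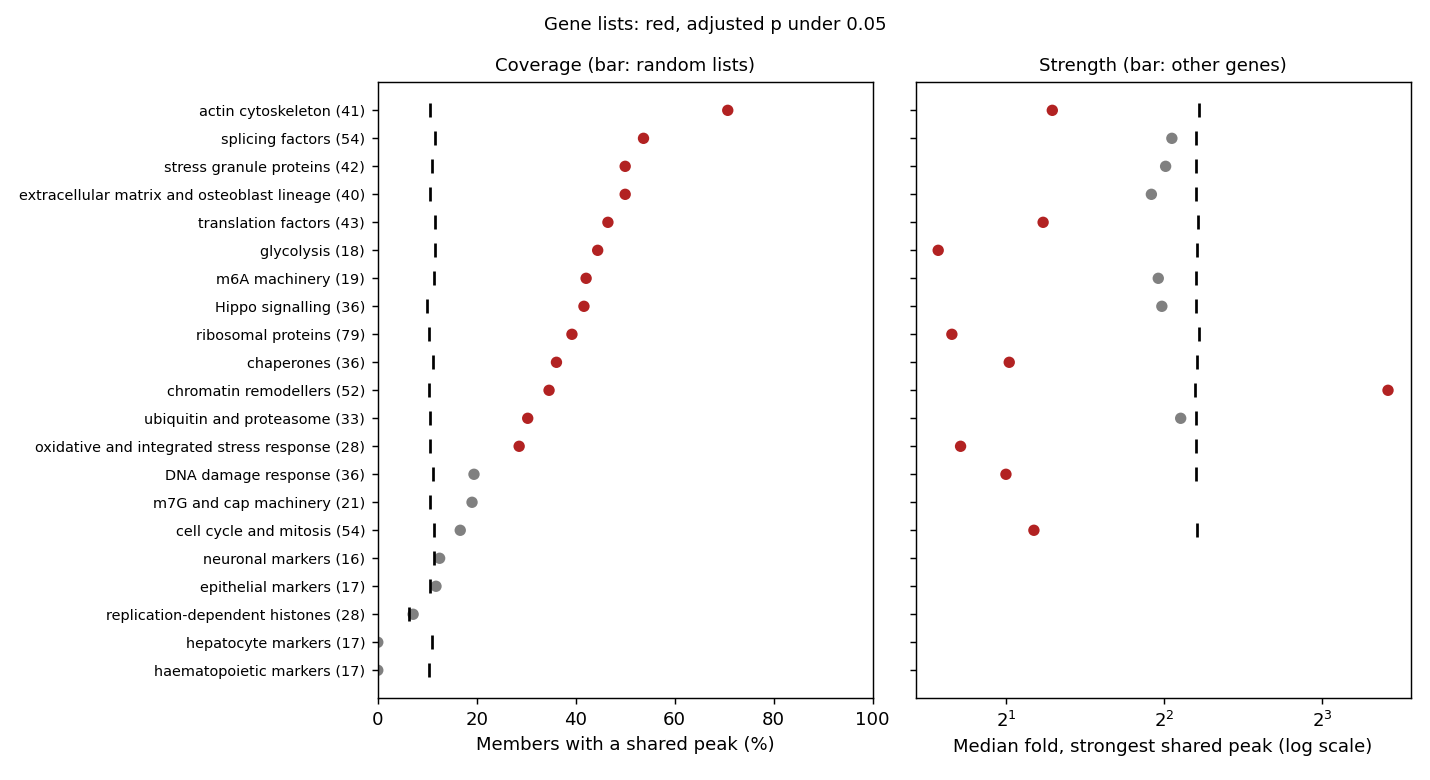
For each fixed gene list (members in brackets), the left panel shows the percent of members with a shared peak and, as a bar, the mean of random lists. The right panel shows the median fold of the strongest shared peak on a log axis with the median of other genes as a bar, for lists with at least 5 such members; red marks an adjusted p under 0.05, as for the actin cytoskeleton at 70.7%.

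Writers, binders and cap proteins of m7G were looked at gene by gene. METTL1 and WDR4, the 2 subunits of the m7G methyltransferase of tRNA, had no peak in either table. QKI, an RNA-binding protein, had a strong peak in both replicates (10.7 and 9.17, log10 p -98.6 and -102), on chromosome 6 from 163414793 to 163415302, plus strand, 330 nt from the annotated gene start. The span of LOC124901234 also covers it. LARP1, which binds the cap of ribosomal protein mRNAs, had 3 shared peaks (5.00 and 3.33 at the strongest), and NCBP2, the small subunit of the nuclear cap-binding complex, had 2.17 and 2.61. The list of m7G and cap machinery as a whole had 4 of 21 members with a shared peak (19.0%, adjusted p = 0.400, permutation), which did not pass.

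The strength of peaks was compared among genes with a shared peak, which leaves out genes that are not expressed. It does not match expression level, and the reads behind a peak can set the lowest fold that passes the threshold. RPL8, for example, had a shared peak at 1.07 and 1.15. Differences in fold between lists may therefore follow abundance, which was not measured. Most lists that differed had low folds. Ribosomal protein mRNAs had a median fold of 1.58 at their strongest shared peak against 4.67 for other genes (log2 difference -1.57, adjusted p = 0.0015, permutation), and glycolysis mRNAs 1.49 against 4.61 (-1.63, adjusted p = 0.00187, permutation). Oxidative and integrated stress response (1.64), DNA damage response (2.00), chaperones (2.03), cell cycle and mitosis (2.26), translation factors (2.35) and the actin cytoskeleton (2.45) were also lower, with adjusted p from 0.00187 to 0.0363 (permutation). Chromatin remodellers alone were higher among the 15 lists tested, at 10.7 against 4.59 (log2 difference 1.22, adjusted p = 0.00187, permutation), with CHD3, SMARCC1, SMARCC2, KMT2B (11.6 and 16.7) and CREBBP (9.87 and 11.7) among the 18 genes. That call ended when all peaks of a single replicate were used, with a difference of 0.41 (adjusted p = 0.0865, permutation) without replicate 1 and 0.06 (adjusted p = 0.834) without replicate 2. It also ended with the mean over a gene's shared peaks (0.37, adjusted p = 0.291, permutation), while the DNA damage call ended without replicate 1 (-0.78, adjusted p = 0.0502) and the oxidative stress call without replicate 2 (-0.71, adjusted p = 0.13). With 50% reciprocal overlap, the DNA damage (adjusted p = 0.0561, permutation), oxidative stress (0.251) and cell cycle calls (0.0561) ended, and the cell cycle call also ended in the more significant peaks (0.201). With that overlap the log2 difference barely moved for DNA damage (-1.26, from -1.20) and cell cycle (-1.02, from -1.03). For oxidative stress it shrank to -0.71 from -1.49. At a fold of at least 4 in both replicates, a setting added after the results had been seen, 0 of the 7 lists with enough genes passed. The remodeller difference was 0.85 (adjusted p = 0.0504, permutation), and the actin cytoskeleton turned to 0.22 above other genes (adjusted p = 0.726, permutation). That filter removes low folds by construction, so it cannot test whether a lower strength holds. Of the lists that differed, only remodellers and the actin cytoskeleton, with 6 of its 29 genes left, could be tested.

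Peaks found in a single replicate numbered 1618 in replicate 1 and 2145 in replicate 2. The highest on protein-coding genes were DSG2, a desmosomal cadherin (111), SIRT3, a mitochondrial deacetylase (92.5), and ZNF507 (92.5) in replicate 1. In replicate 2 they were CD70, CYP24A1 and POLR2E, each at 70. Of these single-replicate peaks 59.2% and 60.1% lay in genes with no peak at all in the other table. They were less significant than shared peaks, with a median log10 p of -4.39 against -7.47 in replicate 1 and -4.50 against -8.27 in replicate 2. Their median fold was 4.50 against 4.11 for shared peaks in replicate 1 and 3.05 against 3.79 in replicate 2.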

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

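Added after the data had been examined were all settings for gene-start peaks, the merging of overlapping peaks, the genes of up to 5000 nt, and the fold of at least 4 for the list results. Sharing stayed above random placement in every setting run, from 49.0% of replicate 1 peaks with 50% reciprocal overlap to 70.2% in the more significant peaks of each table. Reciprocal overlap and midpoints within 100 nt were set against the random share for an overlap of 1 bp, with no placement of their own. Shared peaks numbered 1505 when only those more significant peaks were kept and 1143 at a fold of at least 4 in each table, since fewer peaks entered. The rank correlation of folds was 0.899 with reciprocal overlap and 0.908 in the more significant peaks, and that of significance was 0.685. The odds ratio for shared genes was 94.8 in the more significant peaks. The gene-start difference in log2 fold lay between 0.56 and 0.66 in the 5 alternatives, and the share of peaks near the start was 35.9% at 500 nt, wider by construction, and 19.0 to 22.5% with a replicate left out. Lists with higher coverage numbered 4 at a fold of at least 4, 5 among genes with a peak in either replicate, 11 both with 50% reciprocal overlap and in the more significant peaks, and 14 to 15 with a replicate left out (cell cycle and mitosis gained without either replicate, DNA damage response without replicate 1), against 13. Lists that differed in strength numbered 6 both with 50% reciprocal overlap and in the more significant peaks, and 7 with either replicate left out, against 9. In the more significant peaks only 13 lists had enough genes to be tested, against 15 in the main setting. DNA damage response and oxidative and integrated stress response were not among them, so their calls were not lost there by a test. At a fold of at least 4 the number was 0 of the 7 lists that could be tested. That filter cuts on the tested value, and most of the 9 lists were not among those tested, so the fall to 0 decides nothing. For the 13 lists with higher coverage, 70 of 91 alternative values kept direction and call, 20 lost the call and 1 reversed. For the 9 lists that differed in strength, 34 of 45 kept both, 10 lost the call and 1 reversed. The reversed values were coverage of ribosomal proteins at a fold of at least 4, -2.92 percentage points from random lists (adjusted p = 0.617, permutation), and strength of the actin cytoskeleton at that fold, 0.22 (adjusted p = 0.726, permutation). Both fall under the filter that removes low folds, and the cause was not tested. No paired analysis was possible because the input libraries enter only through the peak calls and the results come from peak lists, so the shared replicate numbers of input and IP could not be used as a block. The planned background of transcripts of at least 1000 nt, and every alternative for transcript regions, the GANGAN motif, hexamers and GC content, were not run, as no transcript models or genome were used here. Unknown depth limits all of this: a gene without a peak was either not enriched or too thinly covered.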

Other observations

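The tests on symbol stems, chromosomes, whole-multiple folds and remodellers, and the comparison of folds with abundant lists, were chosen only after the results had been seen. Among groups of genes that share a symbol stem, collagens stood out. Of 44 COL genes 19 had a shared peak (43.2%, Fisher's exact test, two-sided, adjusted p = 8.69e-07 over 104 stems), against 10.5% of all protein-coding genes. By adjusted p, phosphatase subunits followed, with 25 of 77 PPP genes (32.5%, adjusted p of the same exact test 3.93e-06), then RPL genes (19 of 52, 36.5%) and EIF genes (18 of 56, 32.1%) of the translation machinery. Higher coverage was also seen for ubiquitin-conjugating enzymes with 13 of 42 UBE genes (31.0%, Fisher's exact test, adjusted p = 0.00289), palmitoyltransferases with 8 of 24 ZDHHC genes (33.3%, adjusted p = 0.02) and small GTPases with 17 of 74 RAB genes (23%, adjusted p = 0.0163). Olfactory receptors had 0 of 392 OR genes and zinc finger genes 26 of 517 ZNF genes (5.03%, Fisher's exact test, adjusted p = 0.000167). In all 10 stems were higher and 7 lower, and expression was not measured. By chromosome, coverage was highest on 19 (234 of 1451 genes, 16.1%, Fisher's exact test, adjusted p = 1.88e-10 over 23 chromosomes), and higher also on 22 (14.9%) and 17 (13.5%). It was lower on 4 (6.23%), X (7.19%), 13 (5.62%), 5 (7.96%) and 6 (8.20%).

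The most significant shared peaks, chosen after their values were seen, did not lie on the genes with the highest folds. PTMS, which encodes the acidic nuclear protein parathymosin, had log10 p of -3160 and -3360 with folds of 9.69 and 11.8, and ARPC2 had -2120 and -1860. HNRNPU (-530 and -532), H1-10, which encodes a linker histone (-373 and -401), TGFB1 (-323 and -392) and PTMA, which encodes prothymosin alpha (-316 and -335), came next. FOSL2, a subunit of AP-1, joined high significance (-224 and -231) with high folds (40 and 37.4), as did VGF, a secreted neuropeptide precursor (-181 and -159, with 48.5 and 40.9).

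Of the 20 most significant shared peaks, 4 lay on mRNAs of proteins with long acidic stretches (PTMS, HNRNPU, PTMA and CALR), and 11 such genes, these included, had been noticed by eye. A candidate explanation was their GA-rich coding sequence, tested on 31 other such genes picked from knowledge of the proteins. Of these 18 had a shared peak (58.1% against 10.9% in random lists, permutation p = 0.0002), but their strongest peaks were lower than those of other genes by a median log2 difference of -0.80 (p = 0.0093, permutation). This met the bound set beforehand against sequence, so no higher fold from sequence was seen in these 18 genes. It does not exclude a part for sequence, since expression level was not matched in that comparison. The same genes exceeded the pooled abundant lists in log2 fold by 0.68 (permutation p = 0.00236). That comparison was chosen after the low folds of those lists had been seen, so it decides nothing. Sequence and abundance both stay open, with no biological explanation tested: those lists of ribosomal protein, glycolysis and translation factor genes had 58 of 139 (41.7%), an odds ratio of 1.93 (Fisher's exact test, p = 0.113), and 9 of the 31 genes also belong to the fixed lists.

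Peaks at gene starts may come from the 5′ cap, from few input reads over first exons, or from both. The higher fold there, by 0.60 (permutation p = 1e-05), is what enrichment of the cap would give. Few input reads would make these peaks less significant at equal fold, and they were, by -0.23 in log2 of -log10 p within deciles of fold (permutation p = 8e-05; the prediction named plain -log10 p, and the log was taken because a few peaks have extreme values). Whole-multiple folds, as small counts would give, decided nothing: among peaks with folds high enough to be such multiples, compared at similar fold, gene-start peaks exceeded others by 13.1 percentage points in replicate 1 and 3.75 in replicate 2 (adjusted p = 0.161 and 0.489 over 4 tests, permutation), and without such peaks the difference in fold was 0.50 (permutation p = 1e-05, 2513 peaks). Both explanations stay open, and whether internal m7G near the start adds to them was not tested.

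Chromatin remodeller mRNAs carried higher-fold shared peaks, and position at the gene start or few reads were candidate explanations. Gene-start peaks made up 27.8% of the remodellers' strongest peaks and 28.1% of those of other genes. Within gene-start and other peaks taken apart, the mean log2 difference was 0.61 (p = 0.0178, permutation), against 0.61 without that split (p = 0.0202, permutation), which argues against position as the whole cause. Few reads stay open: within deciles of fold, the remodellers' peaks differed from others by 0.13 in log2 of -log10 p (p = 0.68, permutation) and of those with folds high enough to be whole multiples 0 of 4 and 0 of 8 were, against 44.4% and 25.3% of others (adjusted p = 0.489 and 1 at similar fold, permutation), which decides nothing with so few genes. The pattern itself is fragile, since the median log2 difference, 1.22 over shared peaks, was 0.41 (adjusted p = 0.0865) and 0.06 (adjusted p = 0.834, permutation) when all peaks of a single replicate were used, and no biological explanation was tested.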
